A study of Nicotiana benthamiana with 12 samples.

How the data were processed

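Small RNA was sequenced from leaves of Nicotiana benthamiana, with libraries made from TRIzol-extracted total RNA and HD adapters, per the labels' protocols. HD adapters carry random bases at the ligated ends, which lowers the sequence preference of the RNA ligases. The series covers 12 libraries in 4 groups of 3, and the tables used here hold the 6 wild-type libraries, 3 mock-treated and 3 infected. The NtRDR1 libraries were not analysed here, so the 4 comparisons that need them were not run. Columns were assigned to libraries by the library titles.

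The authors deposited a table of raw counts, the number of reads of each distinct small RNA sequence in each library, with 181521 sequences of 17 to 34 nt. Every count in it was 0 or at least 6, so reads seen fewer than 6 times in a library had been removed, and a 0 stands for 0 to 5 reads. The authors also deposited a table of normalised signal, which equalled the raw count divided by 1 constant per library. Those constants matched DESeq2 size factors computed from the raw counts (2.81, 1.35 and 0.226 for mock libraries 1 to 3, and 1.17, 0.950 and 1.13 for infected libraries 1 to 3). DESeq2 is named in the submitters' processing notes without a version or a role. The normalised table lacks 1 sequence of the raw table and was used only for this check. Adapter trimming, mapping and the genome build are not given in the sources used here. Features are bare sequences with no gene names, and no genome was used. The 20 keyword lists of protein-coding, organelle, virus and other features that were fixed beforehand matched 0 features and gave no result, and no feature was named for a virus.

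The table total per library, 68322 to 2467393 reads, is what remained after low counts were removed and is not the sequencing depth. A listed 0 allows up to 5 reads, which is 2.03 CPM (reads scaled to the library's table total) in the library with the largest table total and 73.2 CPM in mock library 3. Bounds on fold changes assume 5 reads in every library of a group listed at 0, and take the smaller of the ratio of pooled CPM and the ratio of mean CPM. They cover only the removed low counts, not counting error or the spread between libraries. Reads without molecular identifiers are not independent molecules.

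Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit with robust dispersion, TMM factors, filterByExpr by group), with Benjamini-Hochberg adjustment over the sequences tested and a threshold of 0.05. No covariate was used. The test gives no standard error, so SE values are approximate: the absolute log2 fold change divided by the square root of the F statistic. They need not match the p-values exactly. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical. No 2 libraries agreed within sampling noise (chi-square per degree of freedom of 5.45 or more for every pair), so all were counted as separate samples. On simulated counts with the real totals and a dispersion of 0.345, edgeR recovered 66% of 50 sequences changed 16-fold, 24% of 50 changed 8-fold and 0% of those changed 4-fold or 2-fold, with 0 false calls among 21397 tested. At a dispersion of 0.1, with counts under 6 removed, the shares were 90%, 74%, 12% and 0%, with 3 false calls higher and 1 lower among 20159 tested. No simulation joined the dispersion of 0.345 with the removal of low counts. Apart from the changed sequences, all simulated libraries also shared the same mean levels. The simulated false calls therefore do not bound those among the real calls.

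Conserved miRNA families were counted by exact match to a list of 26 families, of which miR6019 and miR6020 had no mature sequence and were not counted, and sums per family were tested with edgeR on the totals and TMM factors of the full table. The share of each family among all reads of listed families was computed as well. Families were grouped as growth and development, RNA silencing pathway, phasiRNA triggers, and nutrient and stress. Groups with at least 5 members were tested with camera (preset correlation 0.01, or estimated) and fry in limma 3.58.1. The share of reads in each length was compared by a two-sided exact permutation test, in which 3 against 3 libraries cannot go below p = 0.1.

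The named families were up to 12 in order of adjusted p. As features had no names, at most 2 risen and 2 fallen sequences were printed. They had the largest fold changes among those called, with a mean of at least 5 CPM and every library of 1 group above every library of the other. The groups, main tests, family list, keyword lists, naming rule and main alternatives were chosen before the data were examined. Those alternatives were DESeq2 1.42.0, other scaling, other filters on low counts, a 2-fold threshold, limma-voom, the replicate number as a block, leaving out each library, other miRNA matching, and other denominators for lengths. The classes of 17 to 19 nt and 25 to 34 nt and a further set of alternatives were added after the data were seen: only 20 to 24 nt, libraries thinned to 68322 reads, at least 6 reads in 2 libraries of a group, the listed families as library size, 1 substituted base in miRNA matching, and leaving out mock libraries 2 and 3 together. Duplex energies were computed with RNAduplex 2.7.2, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.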

Results

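Small RNAs were profiled in leaves of Nicotiana benthamiana, a tobacco relative widely used as a host for plant viruses. Plants were wild type or carried NtRDR1, the tobacco gene for an RNA-dependent RNA polymerase that copies RNA into double-stranded RNA. Each genotype was mock-treated or inoculated with Agrobacterium carrying ToLCV, a geminivirus. The series asked why NtRDR1 plants are less susceptible to this virus, and the comparison available here was infected against mock in wild-type leaves, with 3 libraries per group. The table totals were 2467393, 1245849 and 68322 reads in mock libraries 1 to 3, and 1487531, 1380770 and 1763012 reads in infected libraries 1 to 3. Mock library 3 held 2166 distinct sequences, against 58665 to 102689 in the other mock libraries and 66851 to 76430 in the infected libraries.

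Among conserved miRNAs, the families miR398 and miR397 rose in infected leaves and miR164 fell. miR398, which acts on copper superoxide dismutases, made up 0.407% ± 0.272 (SD, n = 3) of the reads of listed families in mock leaves and 12.1% ± 2.14 (SD, n = 3) in infected leaves. miR397, which acts on laccases, went from 0.411% ± 0.259 to 6.32% ± 1.76 (SD, n = 3 each). miR164, which acts on NAC transcription factors, went from 2.58% ± 0.949 to 0.322% ± 0.107 (SD, n = 3 each). On the scale of the full table, edgeR gave log2 fold changes of 4.57 (SE 1.01, adjusted p = 0.000432) for miR398, 3.70 (SE 1.16, adjusted p = 0.0149) for miR397 and -3.08 (SE 0.93, adjusted p = 0.0144) for miR164. These 3 were the families called among the 22 with counts, while miR399 and miR827 had no counts and miR6019 and miR6020 had no sequence in the list and were not counted. None of the 3 calls held on this scale without mock library 3 or without any single infected library, where 0 families were called. The log2 fold changes there were 3.95 to 4.48 for miR398, 2.89 to 3.54 for miR397 and -3.94 to -3.20 for miR164. miR397 was not called with library totals as the only scaling (log2 fold change 2.98, edgeR adjusted p = 0.117).

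Listed families took 7.73%, 2.19% and 13.1% of the reads of mock libraries 1 to 3, and 5.79%, 4.08% and 4.80% of infected libraries 1 to 3. With the listed families themselves as library size, a scaling added after the data were seen, edgeR called 5 families higher and 4 lower. The higher ones were miR398 (log2 fold change 4.91), miR397 (3.97), miR390 (2.46), miR160 (1.94) and miR393 (0.69), and the lower ones were miR164 (-2.998), miR168 (-2.41), miR403 (-1.43) and miR172 (-1.31). On that scale miR398, miR397, miR164, miR168 and miR403 were called in 6 of 6 fits that left out 1 library each. The other 4 calls did not hold in all of these fits, with miR390 called in 5 of 6, miR393 in 3, miR160 in 2 and miR172 in 1. The shares of 13 of the 22 families did not overlap between the groups, where chance gives 10%.

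Within the nutrient and stress group, 2 of 4 tested families rose. miR408, which acts on copper proteins, held 0.115%, 0% and 0.0892% of listed-family reads in mock libraries 1 to 3, where the 0 allows up to 5 reads, and 0.931% ± 0.0950 (SD, n = 3) in infected leaves (log2 fold change 3.25, SE 1.76, edgeR adjusted p = 0.416). It was called with DESeq2 (4.08, adjusted p = 0.00260), after thinning to equal table totals (3.97), without mock library 2 (2.14) and without mock libraries 2 and 3 (1.83), and without mock library 1 its log2 fold change was 5.04 and it was not called. The edgeR adjusted p over the fits without 1 library ran from 0.000171 to 0.464. The fourth member, miR395, did not pass the test.

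In the RNA silencing group, 0 of 3 families were called on the scale of the full table, where 4 of 22 families had an unadjusted p under 0.05 in edgeR. miR168, which acts on the silencing effector AGO1, held 4.94% ± 1.20 of listed-family reads in mock and 0.933% ± 0.0932 in infected leaves (SD, n = 3 each), with a log2 fold change of -2.63 (SE 1.09, edgeR adjusted p = 0.101). For miR403, which acts on AGO2, the shares were 1.53% ± 0.458 and 0.563% ± 0.0412 (SD, n = 3 each), with a log2 fold change of -1.60 (SE 0.81, edgeR adjusted p = 0.231). Both fell on the listed-family scale, and on the scale of the full table both were called without mock library 2 (-3.52 for miR168 and -2.55 for miR403) and without mock libraries 2 and 3 (-3.94 and -2.71). miR162, which acts on DCL1, had shares of 0.199% ± 0.0459 and 0.298% ± 0.0576 (SD, n = 3 each) and was called on neither scale. Of the 2 phasiRNA triggers with counts, miR390 had a log2 fold change of 2.34 (SE 1.41, edgeR adjusted p = 0.374), which turned to -1.31 when 1 substituted base was allowed in the match. It was called with DESeq2 (3.17) and without mock library 1 (4.01).

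Of 13 growth and development families, miR164 fell and 0 rose on the scale of the full table. The other named members had log2 fold changes of -1.34 for miR172, 1.72 for miR160, -1.01 for miR167, -0.66 for miR319 and 0.63 for miR393, with edgeR adjusted p between 0.433 and 0.691. The direction of miR319 flipped with RLE scaling (0.12), under DESeq2 (0.13) and without mock library 1 (0.097), and that of miR393 without mock library 2 (-0.22) or infected library 1 (-0.011). Without mock library 2, miR172 (-2.37) and miR167 (-1.87) were called lower, as was miR319 (-1.53, and -1.81 without mock libraries 2 and 3), and with DESeq2 miR160 (2.51) was called higher. The auxin response factor family miR167 held 11.7% ± 0.261 of listed-family reads in mock and 6.21% ± 0.490 in infected leaves (SD, n = 3 each). The most abundant families differed less, with miR159 at 33.9% ± 2.77 and 30.1% ± 3.67, and miR396 at 23.04% ± 4.27 and 22.5% ± 4.58 (SD, n = 3 each). On the listed-family scale miR160 and miR393 were called higher and miR164 and miR172 lower, of which only miR164 was called in 6 of 6 fits that left out 1 library each. As a group on the scale of the full table they did not pass the test against the other families (camera p = 0.0860, p = 0.444 with an estimated correlation, and p = 0.0259 without mock library 2), nor did they move one way on balance (fry p = 0.924). Single mature sequences from the list numbered 33 among the sequences tested, and edgeR called 5 higher and 3 lower, with the same counts adjusted over the list alone.

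**Figure D1:**
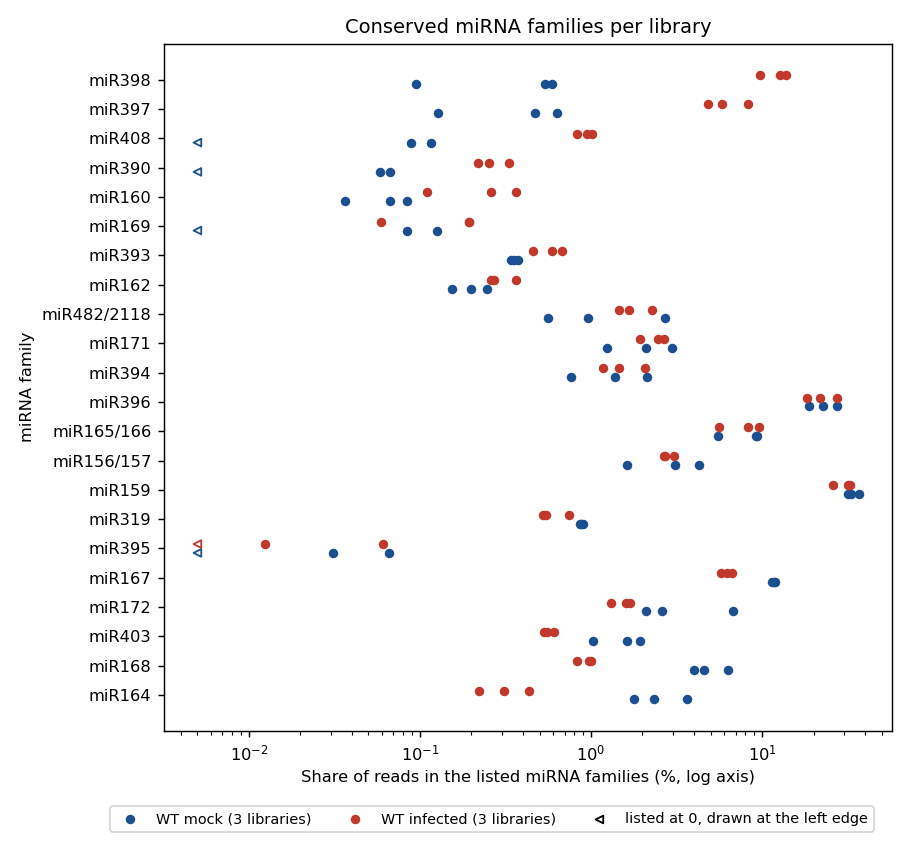
Share of listed-family reads (%, log axis) for each of the 22 miRNA families with counts, with 1 point per library, blue for mock and red for infected, and open triangles for a listed 0. miR398 and miR397 lie at the top of the order by log2 fold change with every infected library above every mock library, and miR164 and miR168 lie at the bottom with every infected library below.

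Reads of 22 nt, the length made by the Dicer-like enzyme DCL2, took a larger share in infected leaves. They made up 13.1% ± 5.85 of reads in mock and 31.5% ± 2.88 in infected leaves (SD, n = 3 each), with 19.04% in the highest mock library and 28.7% in the lowest infected library. The exact permutation p was 0.1, the smallest that 3 against 3 libraries allow (adjusted 0.35 over 7 length classes). The ratio of 22 nt to 24 nt reads was 0.562, 0.166 and 0.659 in mock libraries 1 to 3, and 1.25, 1.75 and 1.53 in infected libraries 1 to 3. Reads of 17 to 19 nt made up 1.57% ± 1.06 and 7.85% ± 2.20 (SD, n = 3 each, exact permutation p = 0.1).

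The other length classes overlapped between the groups, although within 25 to 34 nt the 25 nt reads alone did not (2.10% to 5.12% in mock and 1.72% to 2.001% in infected libraries). Reads of 24 nt, the length made by DCL3, were at 32.5% ± 12.4 in mock and 21.1% ± 1.72 in infected leaves (SD, n = 3 each, exact permutation p = 0.4). Reads of 21 nt, the main length of miRNAs, were at 24.7% ± 17.1 and 21.9% ± 0.910 (SD, n = 3 each, exact permutation p = 0.7). Mock library 2 stood apart, with 6.04% of reads at 21 nt and 36.6% at 25 to 34 nt, against 5.91% and 12.7% at 25 to 34 nt in mock libraries 1 and 3. Without it the difference at 21 nt was -12.2 percentage points in place of -2.85, and that at 25 to 34 nt was -1.06 in place of -10.2.

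**Figure D2:**
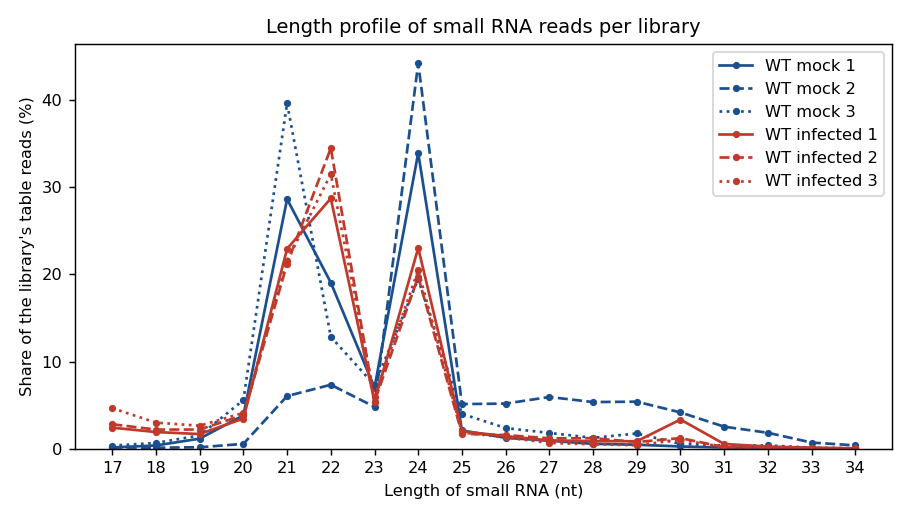
Share of each library's table reads (%) by small RNA length (nt), with 1 line per library, blue for the 3 mock and red for the 3 infected libraries. The infected libraries peak at 22 nt, at 28.7% to 34.4%, above the 7.34% to 19.04% of the mock libraries, and mock library 2 carries 36.6% of its reads at 25 to 34 nt.

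Across single sequences, infected leaves had many more rises than falls. edgeR tested 21240 sequences, which held 68.4% of all reads, and called 5768 higher and 376 lower in infected leaves. Sequences of 22 nt made up 43.3% of the higher calls and 32.7% of those tested, and 36.0% of the 22 nt sequences rose, against 46.9% at 20 nt and 32.0% at 21 nt. Sequences of 17 to 19 nt rose in 85.2% of cases, with a median log2 fold change of 7.33. The shares by length include the 3178 tested sequences listed at 0 in all 3 mock libraries, all of which were called higher. Shares by length were not computed for sequences with reads in both groups, so they do not separate a rise from passage of the filter. Of the 24 nt sequences, 5.54% rose and 1.27% fell, with a median log2 fold change of -0.15. Sequences of 25 to 34 nt were 4.03% of those tested and gave 38.6% of the lower calls, with 149 called higher and 145 lower and a median log2 fold change of 0.02. Sequences that start with T, the first base favoured by AGO1, made up 48.5% of the higher calls and 41.6% of those tested. The shares were 25.3% and 35.7% for A, 14.2% and 11.4% for C, and 11.96% and 11.29% for G. First base was not separated from length, so these shares do not bear on AGO1.

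The median log2 fold change over all sequences tested was 1.23, and it was 1.99 with RLE scaling and 1.17 with library totals. It was 5.75 without mock library 1, 0.61 after thinning to equal table totals, 0.33 without mock libraries 2 and 3, and -0.16 with no filter on low counts, over all 181521 sequences. All 3178 tested sequences listed at 0 in all 3 mock libraries were called higher and all 46 listed at 0 in all 3 infected libraries were called lower, since such sequences passed the filter only through the other group. Among sequences with reads in both groups, 2590 were called higher and 330 lower. Only 2114 tested sequences had 6 or more reads in mock library 3, and 341 of the 376 lower calls were among them. Without mock library 3 the counts were 7089 higher and 2720 lower. Without mock library 1 they were 14836 and 559, without mock library 2 7485 and 1563, and without infected libraries 1, 2 or 3 5707 and 2184, 4939 and 2076, and 4450 and 1917.

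**Figure D3:**
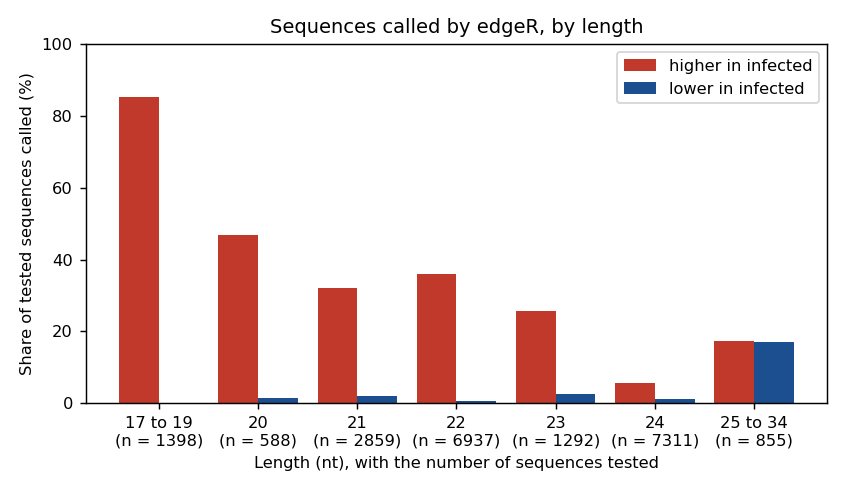
Share of tested sequences (%) that edgeR called higher (red) or lower (blue) in infected leaves, by length class (nt), with the number tested under each class. The share called higher was 85.2% at 17 to 19 nt, 46.9% at 20 nt, 32.0% at 21 nt, 36.0% at 22 nt, 25.7% at 23 nt and 5.54% at 24 nt, and at 25 to 34 nt 17.4% were called higher and 16.96% lower.

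The risen sequences with the largest fold changes under the naming rule were a 21 nt and a 20 nt sequence listed at 0 in all 3 mock libraries. TGGTGACTTTGGTCTCGAAAG had 4035, 1823 and 2337 reads in infected libraries 1 to 3, at least 67.6-fold higher than in mock (edgeR adjusted p = 7.37e-08). TTGGGACCAAAGTCACCAGC had 1242, 977 and 1042 reads, at least 26.9-fold higher (edgeR adjusted p = 9.02e-07). The fallen sequences were listed at 0 in all 3 infected libraries. ATTATGACTGAACGCCTCTAAGTCAGA, of 27 nt, had 56, 305 and 9 reads in mock libraries 1 to 3, at least 30.2-fold higher than in infected leaves (edgeR adjusted p = 2.39e-05). AAGTATGAACAAATTCAGACTGTGAAAC, of 28 nt, had 46, 272 and 6 reads, at least 26.5-fold higher (edgeR adjusted p = 4.20e-05). Mock library 2 held most of the mock reads of both fallen sequences, and the bounds were not computed without it. Without that library the log2 fold change was -8.87 in place of -10.2 for the 27 nt sequence. For the 28 nt sequence it was -8.43 in place of -9.95, and both were still called lower. The deposited data do not pair the risen or fallen sequences with genes or positions.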

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

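The alternatives described as added were chosen after the data were seen; the rest were chosen beforehand. The counts of 5768 sequences higher and 376 lower were 13515 and 834 with DESeq2, 8951 and 576 with limma-voom, and 3428 and 1702 with no filter on low counts. With RLE factors 10398 were higher, with library totals only 955 were lower, and with at least 10 counts in every library of 1 group 833 were lower. Of the added alternatives, only 20 to 24 nt gave 3589 and 677, and thinning to the smallest total gave 246 and 64, out of 1103 tested. At least 6 reads in 2 libraries of a group gave 1760 lower, and leaving out mock libraries 2 and 3 together gave 1962 lower. Leaving out each library gave 4450 to 14836 higher and 559 to 2720 lower. Higher calls outnumbered lower calls in each of these alternatives. The number of sequences tested also differed, from 21240 in the main fit to 54791 with DESeq2 and 181521 with no filter. It was 28038 to 35627 on leaving out each library, and fewer were tested after thinning. How far this accounts for the changes was not tested.

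Deviations of libraries with the same replicate number correlated at 0.00799, -0.111 and 0.0828. These values gave no sign of pairing but cannot exclude a shared batch. With the replicate block the counts were 98 higher and 28 lower, and 0 miRNA families were lower.

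The counts of 2 miRNA families higher and 1 lower became 1 higher with library totals, 5 higher with DESeq2, and 5 higher and 4 lower with the listed families as library size (added). Without mock libraries 2 and 3 together (added) 9 were lower. Leaving out each library gave 0 to 3 higher and 0 to 12 lower, with 12 lower without mock library 2. Of the values for the 12 named families under the alternatives, 136 kept direction and side of the threshold, 23 passed it, 14 no longer passed it and 7 reversed. The reversals were miR319 with RLE factors (0.12), with DESeq2 (0.13) and without mock library 1 (0.097), miR390 with 1 substituted base allowed (-1.31), and miR393 without mock library 2 (-0.22), without infected library 1 (-0.011) and without mock libraries 2 and 3 (-0.44). On leaving out each library miR319 ranged from -1.53 to 0.097 and miR393 from -0.22 to 1.32. The cause was not tested. All 66 values for the 4 named sequences kept direction and side. The camera p of the growth and development families was 0.0259 to 0.394 on leaving out each library, lowest without mock library 2, and 0.265 with the listed families as library size.

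The difference in 22 nt share, 18.5 percentage points, was 23.1 when distinct sequences were counted, 13.9 after thinning and 15.6 to 21.5 on leaving out each library. Counting distinct sequences reversed 21 nt from -2.85 to 3.70 and 23 nt from -0.785 to 1.09, and moved 24 nt to -23.6. Thinning moved 23 nt to -2.34. The range on leaving out each library was 5.05 to 7.19 for 17 to 19 nt, -0.895 to 1.61 for 20 nt, -12.2 to 4.57 for 21 nt, -1.57 to -0.323 for 23 nt, -18.0 to -5.60 for 24 nt and -16.4 to -1.06 for 25 to 34 nt. Not run were the comparisons with NtRDR1 libraries, viral features and keyword lists, which had no values, and a fit over all groups, which here is the main fit. The small table total of mock library 3 limits its values, as only 2114 of the 21240 tested sequences had 6 or more reads there.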

Other observations

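The tests in this part were chosen after the results they bear on were seen, apart from the fits on the full-table scale that leave out 1 library, which were planned. The most abundant risen sequences not covered by the naming rule formed a small set related to the named ones, chosen here after their values were seen. TTTGGGACCAAAGTCACCAGC, which holds the named 20 nt sequence, had 32, 0 and 0 reads in mock libraries 1 to 3 and 25354, 19405 and 21505 in infected libraries 1 to 3. A close variant, TTTGGGACCAAAGTCACCAAC, had 164, 9 and 11 reads in mock and 6780, 4376 and 6133 in infected leaves. A hypothesis is that the first of these and TGGTGACTTTGGTCTCGAAAG are the 2 strands of a duplex cut by a Dicer-like enzyme, as in a miRNA. RNAduplex paired 19 bases at -31.9 kcal/mol and left 2 unpaired bases at each 3′ end, and 0 of 1000 random 21 nt partners from the table bound as strongly (the lowest was -27.4 kcal/mol). This is consistent with such a duplex, but no precursor was examined, and the pair was picked because the sequences looked complementary.

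The risen sequences of 20 to 24 nt also joined into longer stretches. Chaining words of 14 nt from both strands, 1 base at a time, gave 13 contigs of at least 100 nt, the longest of 259 nt. At most 9 such contigs came from any of 20 length-matched draws of sequences that were not called. The called set entered whole, while each draw was a random part of the uncalled sequences, which favours fewer contigs in the draws. Reads on the 13 contigs were 64.7% to 85.2% of 22 nt, and 28.4% to 61.4% came from 1 strand, which may reflect loci copied into double-stranded RNA. These shares were not computed for the contigs of the draws. Mock reads lay on each of the 13 contigs, from 181 to 5088 per contig. Pooled, the contigs held 5334 CPM in mock and 44543 CPM in infected leaves, so their reads were not confined to infected libraries. How the mock reads fell over the mock libraries was not computed. A protein-coding source was left undecided. Open frames were not longer than in shuffled copies (lowest adjusted p = 0.462 from 1000 shuffles per contig). However, they spanned 97.1% to 99.4% of each contig except those of 259 nt and 147 nt (66.0% and 67.3%). A longer frame was thus hardly possible in most contigs, and the test could not settle the source. A retroelement source was tested with 4 protein motifs in the 39 contigs of at least 50 nt. A protease motif was found, and 96 of 1000 shuffled sets held as many motifs, so this too stays undecided.

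The first pattern weighed is the excess of higher over lower calls, 93.9% of calls and 88.7% of those with reads in both groups. Of the 2590 higher calls with reads in both groups, 2015 had mock reads in mock library 1 alone. With no filter on low counts 66.8% of calls were higher, and how far the filter accounts for the excess was not tested. For 3 other explanations, each taken alone, the excess became smaller but remained. Without mock library 3, which had the smallest table total, the share was 72.3%. It was 82.7% without mock library 2 with its long fragments, and 79.4% with all libraries thinned to the smallest total. All 3 fits kept the filter on low counts. They therefore cannot set aside any of the 3 explanations acting together with that filter. Virus-derived sequences stay open: 44.9% of the higher calls had reads in a mock library, but 9.97% had them outside mock library 1, so this rests largely on 1 library. Of the 10 splits of the 6 libraries, 1, the real one, gave as many as 6144 calls and the highest other gave 2, but 10 splits are too few for a share under 0.05. Correlations of log2 counts across sequences were 0.62 to 0.63 between infected libraries and 0.31 to 0.34 between mock libraries.

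The second pattern is the opposite movement of miRNA families. Scaling of the libraries is argued against as the whole cause, since 3 of the 3 called families, miR398, miR397 and miR164, were called the same way with the listed families as library size. The long fragments of mock library 2 are argued against too, since 3 of the 3 were called the same way without it on that scale. The real split called 3 families and the highest other split 0; it was 1 of 10, too few for a share under 0.05. A response to infection stays open as a hypothesis, with miR398 at a log2 fold change of 4.91 on that scale.

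The third pattern is the larger share of 22 nt reads. After thinning, with low counts removed again, the lowest infected library was still 4.23 percentage points above the highest mock library, which argues against unequal table totals as the whole cause. Among reads of 20 to 24 nt alone the gap was 13.8 percentage points, which argues against the long fragments of mock library 2. Virus-derived reads stay open, as the table names none. The nonanucleotide found in the origin of geminiviruses occurred in 9 sequences, 4 found only in infected libraries (72 reads) and 5 only in mock libraries (39 reads). So short a motif also occurs by chance, at a rate not computed here, so these counts decide nothing. After that thinning the 24 nt share also did not overlap, at 15.95% to 26.2% in mock and 12.5% to 13.6% in infected libraries, nor did the 23 nt share, at 5.36% to 7.41% and 4.14% to 4.64%.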
